A study of Mus musculus with 6 samples.

How the data were processed

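Messenger RNA of sorted RELM-α+ peritoneal macrophages of mice was captured on beads, broken by heat, reverse transcribed, amplified by PCR and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The groups, KO and WT with 3 libraries each, were taken from the sample titles. The submitters' processing notes name fastp 0.18.0 for the reads and the genome build GRCm39. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. The coordinates in the deposited table are those of GRCm38, not GRCm39: of 15426 genes matched by gene ID to the RefSeq gene table of GRCm38.p6, 13131 had the same start. All coordinates given here are the table's own, with chromosome numbers read from that RefSeq table. Reads shared by paralogs, pseudogenes or overlapping genes may have been split between them, since the counting is not described.

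The authors deposited 1 table with an estimated count of reads per gene and library, not normalized, per the file headers. Between 4.82% and 5.49% of the cells of a library were not whole numbers, so these values are estimates and were rounded to whole counts before any count test. The authors also deposited FPKM and TPM values of the same libraries, per the file headers; they were not used for tests. The log2 fold changes and the p-values and q-values in the authors' deposited table come from DESeq2, per the file headers, with no version given. Only the number of its genes past a q-value of 0.05 and their direction were used. No columns of other samples were present. The table listed 15469 protein-coding genes.

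The depth was 17280855 to 18632623 counts per library. Genes with enough counts by filterByExpr of edgeR (minimum count of 10) were kept, which left 11424 for testing and 4045 not tested. Counts were scaled with TMM factors, and the groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, R 4.3.3), with group as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Differences are given as KO minus WT in log2 or as KO divided by WT, levels as CPM on the TMM-scaled library sizes with the SD of 3 libraries. Where a group held very few counts, the ratio of group totals is given with an exact 95% binomial interval, and a group at 0 is set to a floor of 3 counts per library.

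The design, the rule for named genes, the gene lists and the main set of alternatives were fixed before the data were examined. The rule named Spi1 and Retnla, then the 8 genes that rose and the 8 that fell most among called genes with a mean of at least 10 CPM and no overlap between the groups. It left out predicted genes, pseudogenes and immunoglobulin or T cell receptor segments. From each list it took up to 3 called members with the largest change and a mean of at least 1 CPM, or, with none called, the member with the smallest p. Other genes are said to have been chosen after their values were seen.

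There were 30 lists. The 18 gene lists were ferroptosis suppressors, ferroptosis drivers, iron handling, myeloid genes known as PU.1 targets, large peritoneal macrophage genes, small peritoneal macrophage and monocyte genes, alternative activation, inflammatory cytokines and mediators, interferon-stimulated genes, MHC class II presentation, phagocytosis with efferocytosis and lysosome, cell cycle, glycolysis and hypoxia, cholesterol synthesis, ATF4 and unfolded protein response, ETS factors other than PU.1, other myeloid transcription factors, and dissociation and immediate early genes. The 12 marker lists were B cell, T and NK cell, neutrophil, eosinophil, mast cell, dendritic cell, mesothelial cell, fibroblast, endothelial cell, erythroid cell, platelet and megakaryocyte, and osteoclast. The 19 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. Camera asks whether the genes of a list stand apart from all other genes. Fry, an alternative, asks whether the genes of a list move one way on balance and does not compare them with other genes. The 2400 KEGG, Reactome and GO terms in the table with 15 to 500 tested genes were tested with camera in the same way. Shares of counts were compared with an exact permutation test over the 20 assignments of the libraries.

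The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0 (on the 15450 genes with a count, with its own independent filtering), limma-voom, no filter, a mean of at least 10 CPM, the replicate number as a block, each library left out in turn, an added 2-fold threshold, an adjusted p under 0.01, camera with an estimated correlation, and fry. A correction for GC content and transcript length with smooth terms per library (mgcv 1.9.3) and a fit without genes of the X and Y chromosomes were added later. The fit was tested on simulated data with 11424 genes, of which 100 were changed 2-fold and 100 changed 4-fold. With the spread of both groups it recovered 24% of the 2-fold and 80% of the 4-fold genes with 4 false calls, and with the spread of the WT libraries 96% and 100% with 22 false calls. In the same simulated comparison of 11424 genes, camera gave a list of 25 genes changed 2-fold a p of 2.2e-36 and gave 0 of 100 random lists a p under 0.05. The simulated genes varied independently of one another. This check therefore cannot show how often camera calls lists of correlated genes by error, and the cell cycle list had an estimated correlation of 0.842.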

Results

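RNA was measured in 6 libraries of mouse peritoneal macrophages, the phagocytes of the abdominal cavity. The cells came from mice of the CAIA model, a name the labels give only as an abbreviation. Cells carrying RELM-α, a secreted resistin-like protein often used as a marker of alternatively activated macrophages, were sorted and plated in culture. There were 3 libraries labelled KO, from cells described as deleted for PU.1, and 3 labelled WT, from control cells. PU.1, encoded by Spi1, is an ETS-family transcription factor needed for the development of macrophages and other myeloid cells. The comparison of the 2 groups was made to ask how PU.1 acts on ferroptosis, an iron-dependent form of cell death driven by oxidised lipids, in these macrophages. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

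The libraries held 17280855, 18632623 and 18258489 counts for KO replicates 1, 2 and 3, and 18033122, 18081143 and 17610236 counts for WT replicates 1, 2 and 3. Across genes, the log2 CPM (counts scaled to a common library size) of the WT libraries correlated with one another at Pearson's r of 0.988 to 0.993, and KO replicates 2 and 3 at 0.99. KO replicate 1 correlated at 0.902 and 0.922 with KO replicates 2 and 3, and at 0.955 to 0.959 with the WT libraries. On the first principal component, which held 71.1% of the variance, KO replicates 2 and 3 lay at 73.2 and 57.5, KO replicate 1 at -22.4 and the WT libraries between -44.9 and -30.8. On the second, with 20% of the variance, KO replicate 1 lay at -54 and the other 5 libraries between 1.44 and 19.5. Genes are not independent replicates, and these correlations describe the libraries only. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 6.55 or more, so no pair was treated as 1 library deposited a second time. That test does not show whether the samples are biologically separate.

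Transcripts of the targeted gene were not lost from the libraries labelled KO. Spi1 (gene ID 20375, chromosome 2, 91082368 to 91115759, plus strand, GRCm38) was at 276.9, 285.5 and 319.7 CPM in KO replicates 1, 2 and 3, and at 323.4, 340.2 and 283.7 CPM in WT replicates 1, 2 and 3. The group means were 294 ± 22.6 and 315.8 ± 29 CPM (SD, n = 3 each), a fold of 0.931 and a log2 difference of -0.10 (SE 0.106, 95% interval -0.363 to 0.156; edgeR quasi-likelihood test, adjusted p = 0.561). The gene count therefore goes against the label of a deletion as far as the amount of transcript is concerned. Counts per gene do not separate exons, and deletion of a part of Spi1 that leaves the rest of the transcript would not be seen in them. The groups are called the libraries labelled KO and labelled WT below, and every direction is a direction between those labels. Retnla, which encodes RELM-α, was not analysed here.

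The Y-linked genes separated the labels completely. All 4 tested genes of the Y chromosome were called lower in the libraries labelled KO. Ddx3y (an RNA helicase, 1260715 to 1286628 on chromosome Y) had 2, 0 and 0 counts in KO replicates 1, 2 and 3 against 3019 in the WT libraries together, a 1680-fold difference (95% counting interval 464 to 13900). Eif2s3y (a translation initiation factor subunit, 1010562 to 1049134) had 2, 0 and 1 counts against 1672, a 619-fold difference (211 to 3010). Uty (a histone demethylase paralog, 1085187 to 1245773) had 4, 1 and 2 counts against 1172, a 186-fold difference (90 to 464). Kdm5d (a histone demethylase, 897566 to 943813) had 0 counts in all 3 KO libraries against 1313, which is at least 162-fold lower at a floor of 3 counts per library. These intervals and floors cover counting error only, because PCR-amplified reads without molecular identifiers are not independent molecules. The adjusted p of these 4 genes lay between 0.00307 and 0.00693 by edgeR. When single libraries were left out, Eif2s3y and Uty stayed called each time, Kdm5d was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0568, 0.0887 and 0.0702), and Ddx3y without WT replicate 2 or 3 (0.0571 and 0.0617).

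**Figure D1:**
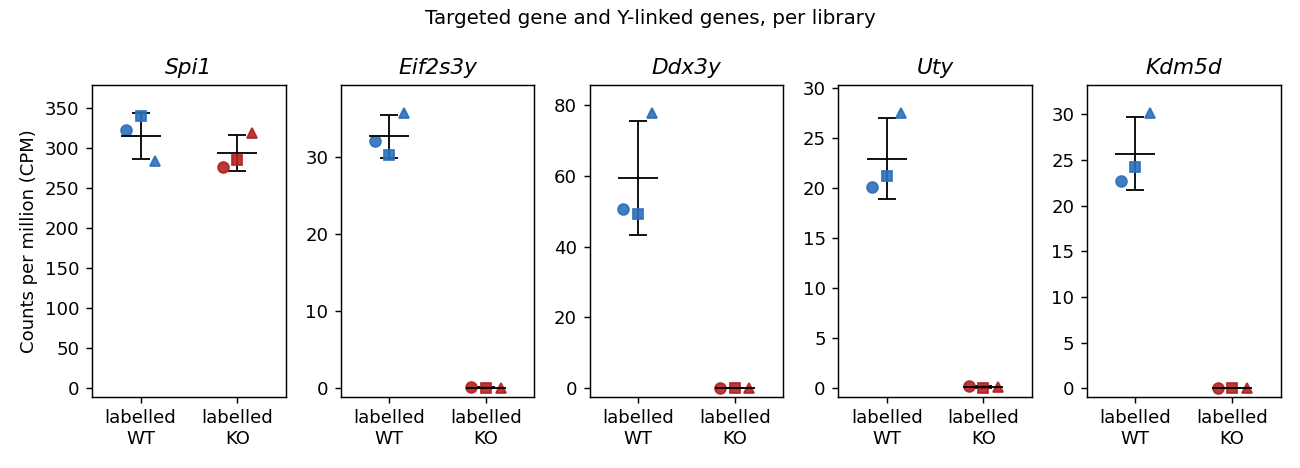
CPM of Spi1 and of the 4 Y-linked genes in each library (points; circle, square and triangle for replicates 1, 2 and 3), with bars for the group mean and whiskers for the SD of 3 libraries, KO-labelled in red and WT-labelled in blue. Spi1 lies between 276.9 and 340.2 CPM in all 6 libraries, while the Y-linked genes lie between 20.1 and 77.8 CPM in the WT libraries and near 0 in the KO libraries.

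Away from the Y chromosome, and among called genes with a mean of at least 10 CPM and no overlap between the groups, the libraries labelled KO differed most by higher Cx3cr1, Dmpk, Spn and Marcksl1 and lower Itga2b, Angptl4, Ctsk and Atp6v0d2. Of 11424 genes tested, 379 were called, 258 higher and 121 lower in the libraries labelled KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Cx3cr1 (chromosome 9, 120048683 to 120068296), the receptor for fractalkine, rose 25-fold, from 2.08 ± 1.1 to 52.1 ± 1.7 CPM (log2 difference 4.64, SE 0.386, adjusted p = 0.0126). Spn (chromosome 7, 127123637 to 127145552), which encodes the leukocyte surface sialomucin CD43, rose 16.5-fold, from 2.19 ± 0.22 to 36.3 ± 6.75 CPM (log2 4.05, SE 0.197, adjusted p = 0.00307). Marcksl1, an actin-binding protein kinase C substrate, rose 10.6-fold to 62.6 ± 1.7 CPM. Dmpk, the kinase gene of myotonic dystrophy, and its neighbour Dmwd rose 17.5-fold and 8.12-fold, from adjacent positions on chromosome 7 (19083646 to 19093821 and 19076112 to 19082778). Ifi27l2a, an interferon-inducible gene that overlaps Ifi27 in the table's coordinates, rose 9.74-fold, Lmnb1, which encodes lamin B1, 8.11-fold, and Top2a, which encodes topoisomerase 2 alpha, 5.56-fold. KO replicate 1 was the lowest of the KO libraries for Dmpk, Spn, Ifi27l2a, Dmwd, Lmnb1 and Top2a, with 9.03 CPM of Lmnb1 against 37.7 and 29.5 CPM in replicates 2 and 3. Lmnb1 lay at the threshold by edgeR (adjusted p = 0.0499) and was not called with RLE factors (0.0506), without a filter (0.0591), with a mean of at least 10 CPM (0.0557) or by limma-voom (0.131). By limma-voom Dmpk and Top2a were not called either (0.0832 and 0.0588, against 0.0378 and 0.0387 by edgeR).

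Besides the 4 Y-linked genes, the genes that fell furthest under the naming rule were Itga2b, Angptl4, Ctsk and Atp6v0d2. Itga2b, the integrin alpha chain of the platelet fibrinogen receptor, fell from 31.2 ± 9.96 to 2.14 ± 1.96 CPM, a fold of 0.0686 (adjusted p = 0.0482). Without KO replicate 1 its log2 difference went from -3.87 to -4.92. Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 45.9 ± 5.79 to 6.34 ± 0.939 CPM, a fold of 0.138 (log2 -2.85, SE 0.164, adjusted p = 0.00345). Ctsk, the collagen-degrading protease cathepsin K, fell to 0.174 of its WT level (66 ± 6.19 to 11.5 ± 3.98 CPM), and Atp6v0d2, a subunit of the proton pump of lysosomes and osteoclasts, to 0.185 (811.6 ± 165 to 149.9 ± 28.8 CPM). The listed range of Atp6v0d2 (chromosome 4, 19876838 to 19922566) lies within those of other table entries such as Zfp984. These entries also take in Sesn2 (132488822 to 132510456), so their listed ranges are too wide to show that reads were shared. Itga2b was not called by edgeR without a filter (adjusted p = 0.0536) or with a mean of at least 10 CPM (0.0557), and the GC and length correction moved the log2 difference of Atp6v0d2 from -2.44 to -1.76 (0.0383).

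The number of called genes rested on which libraries were compared. Without KO replicate 1 it was 5793 of 11677 genes tested (2761 higher and 3032 lower), and without KO replicate 2, KO replicate 3, WT replicate 1, WT replicate 2 or WT replicate 3 it was 15, 11, 14, 5 or 7. All 379 genes kept their direction and an unadjusted p under 0.05 in each of these 6 fits, and all 379 stayed called without KO replicate 1. The 379 genes were chosen from these same libraries at an adjusted p under 0.05. Keeping an unadjusted p under 0.05 with 1 library left out is therefore no independent support, here or for the lists below. Counts of list members called without KO replicate 1, and called genes that stayed called there, need to be read against that large share over all genes. Of the 8 top genes that rose, 2 stayed called without each of the other 5 libraries. Of the 8 that fell, 5 stayed called without KO replicate 2, 6 without KO replicate 3, and 5, 2 and 3 without WT replicates 1, 2 and 3. A correction for GC content and transcript length moved the split to 390 higher and 333 lower, 53.9% higher against 68.1%. It was run on all 6 libraries and not without KO replicate 1. Between KO replicates 2 and 3 and WT, GC content and length explained 23.2% of the variance. The authors' deposited table, made with DESeq2, held 1238 genes at a q-value under 0.05, 816 of them higher and 422 lower in KO, and all 379 genes called here were among them with the same direction.

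Of the ferroptosis genes, 2 changed between the labels, and both belong to the list of drivers. Tfrc (chromosome 16, 32608896 to 32632794), the transferrin receptor that imports iron, fell from 139.6 ± 20.5 to 31.6 ± 11.3 CPM, a fold of 0.226 (log2 -2.14, SE 0.311, edgeR adjusted p = 0.0334). Alox5 (chromosome 6, 116410071 to 116461178), the arachidonate 5-lipoxygenase that oxidises polyunsaturated lipids, rose from 6.75 ± 2.51 to 21.9 ± 2.57 CPM, 3.24-fold (log2 1.70, SE 0.276, adjusted p = 0.0396). Of the 22 drivers tested, these were the 1 higher and 1 lower, and adjusted over the list alone 1 was higher and 2 were lower. DESeq2 called 5 drivers, 1 higher and 4 lower, and without KO replicate 1 edgeR called 6 higher and 11 lower. Camera gave the list as a whole an adjusted p of 0.568, or 0.808 with an estimated correlation. The GC and length correction moved the log2 difference of Tfrc from -2.14 to -1.39 (adjusted p = 0.0473). Both genes stayed called without KO replicate 1, Tfrc alone without KO replicate 2 (adjusted p = 0.0311), and neither without KO replicate 3 or WT replicate 1, 2 or 3, where Tfrc was at 0.109, 0.143, 0.177 and 0.132 and Alox5 at 0.154, 0.0568, 0.239 and 0.14. Alox12, the arachidonate 12-lipoxygenase of platelets, was at 0.307 ± 0.333 against 7.13 ± 2.93 CPM (adjusted p = 0.0609). Of the platelet and megakaryocyte markers, Itga2b was at 2.14 ± 1.96 against 31.2 ± 9.96 CPM and Ppbp at 1.68 ± 2.6 against 26.7 ± 8.34 CPM (adjusted p = 0.137), while Pf4 was at 25.2 ± 17.1 against 19 ± 2.46 CPM (0.598).

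No ferroptosis suppressor was called in the comparison of all 6 libraries. Of 24 tested, edgeR called 0 over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05 (1 higher and 2 lower). DESeq2 called 3 (1 higher and 2 lower) and limma-voom 0. The member with the smallest p was Mboat1, a phospholipid acyltransferase, at 4 ± 0.711 against 1.86 ± 0.15 CPM (fold 2.15, adjusted p = 0.0606; 0.00768 by DESeq2 and 0.0431 with the GC and length correction). Gpx4, the peroxidase that reduces lipid peroxides, was at 278.1 ± 6.69 against 330 ± 41.4 CPM (adjusted p = 0.255), and Fth1, the ferritin heavy chain, at 19200 ± 1530 against 28850 ± 3410 CPM (0.0773). Slc7a11, the cystine importer of the glutathione system, was at 333.6 CPM in KO replicate 1 but 12.7 and 15.8 CPM in KO replicates 2 and 3, against 182.3 ± 38.8 CPM in the WT libraries (adjusted p = 0.781). KO replicate 1 was likewise at or above the WT level, and KO replicates 2 and 3 below it, for Gclm (510.2 CPM, then 110.2 and 101.1, against 350.9 ± 72.9), Srxn1 (682.3, then 207.8 and 196.3, against 580.1 ± 21.9) and Prdx1 (6256, then 2652 and 2388, against 6055 ± 274). Gpx4, Fth1, Slc7a11, Gclm, Srxn1, Prdx1, Alox12, Ppbp and Pf4 were chosen after their values were seen. Camera gave the suppressors the direction down with an adjusted p of 0.133, or 0.808 with an estimated correlation. Without KO replicate 1 that p was 0.00636, and 1 suppressor was higher and 14 were lower, Slc7a11 among them with a log2 difference of -3.66 (adjusted p = 5.46e-05). That fit was not corrected for GC content and transcript length, which explained 23.2% of the variance between KO replicates 2 and 3 and WT.

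Of 22 iron handling genes, edgeR called 1 lower and 0 higher, the called gene being Tfrc, while DESeq2 called 3 lower and 1 higher and limma-voom 1 lower. Adjusted over the list alone, 1 was higher and 2 were lower, and camera gave an adjusted p of 0.293 (0.624 with an estimated correlation). Hmox1, the haem oxygenase that frees iron from haem, was at 1403 CPM in KO replicate 1, 433.2 and 449.6 in KO replicates 2 and 3, and 1468 ± 365 in the WT libraries (adjusted p = 0.325; chosen after its values were seen). Tfrc stayed called without KO replicate 1 or KO replicate 2 (adjusted p = 0.00156 and 0.0311) and was lost without KO replicate 3 or WT replicate 1, 2 or 3 (0.109, 0.143, 0.177 and 0.132). When KO replicate 1 was left out, 4 iron handling genes were higher and 11 lower, and with the GC and length correction the log2 difference of Tfrc was -1.39.

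**Figure D2:**
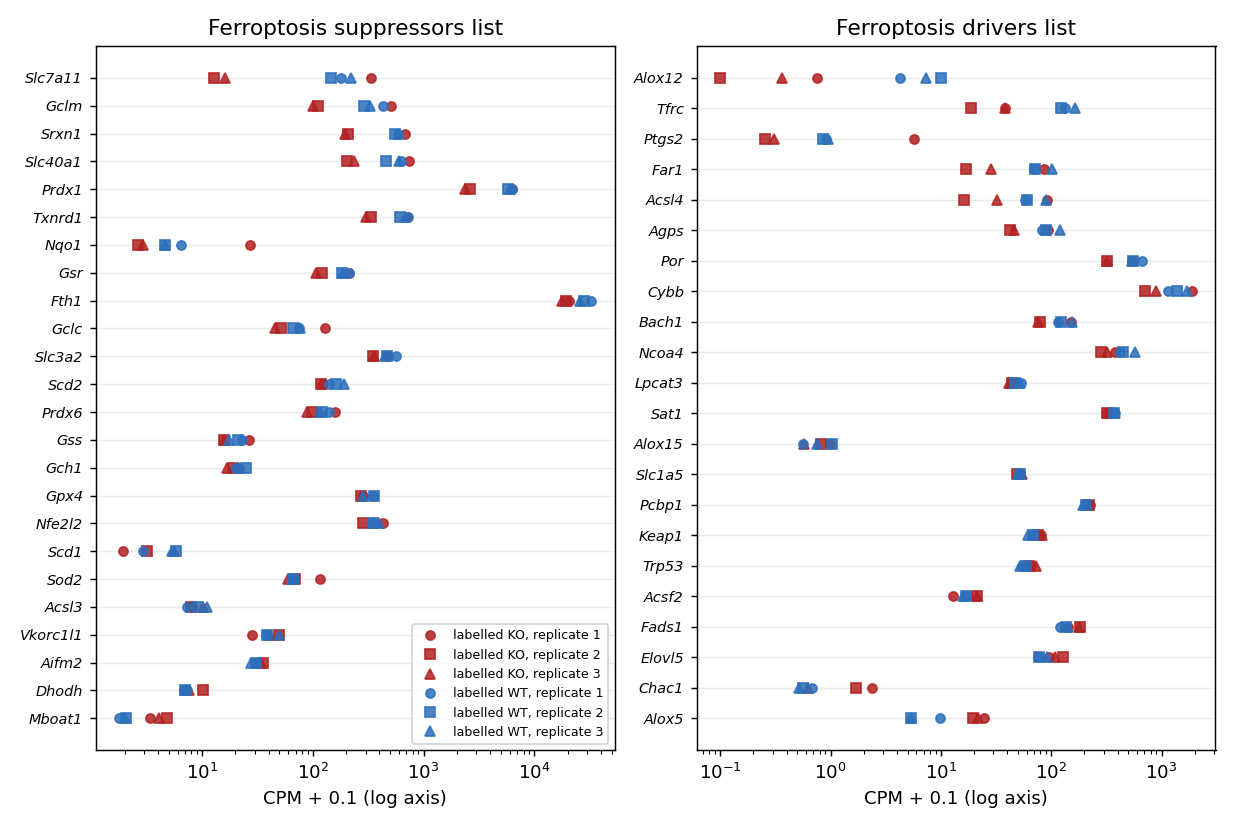
Level of each tested ferroptosis suppressor and driver (y axis) in each library, as CPM + 0.1 on a log axis, with KO-labelled libraries in red, WT-labelled in blue, and circle, square and triangle for replicates 1, 2 and 3. For Slc7a11, Gclm, Srxn1 and Prdx1 the red circle of KO replicate 1 lies among or above the blue points, and the red squares and triangles lie below them.

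Genes known as targets of PU.1 moved in both directions. Of 30 tested, 2 rose and 3 fell, and adjusted over the list alone 5 were higher and 5 lower. Tlr2, the receptor for bacterial lipoproteins, rose 2.09-fold to 101.7 ± 9.42 CPM (log2 1.06, SE 0.103, edgeR adjusted p = 0.0147), and Csf1r, the receptor for macrophage colony-stimulating factor, 1.72-fold to 2694 ± 179 CPM (adjusted p = 0.0208). Ctss, the antigen-processing protease cathepsin S, fell from 9543 ± 357 to 3731 ± 627 CPM, a fold of 0.391 (log2 -1.35, SE 0.151, adjusted p = 0.0196). Cebpa, a myeloid transcription factor, fell to 0.599 of its WT level and Csf2ra, a GM-CSF receptor chain chosen after its values were seen, to 0.673. Cebpa was not called with upper-quartile factors (adjusted p = 0.0886), without a filter (0.0511) or with a mean of at least 10 CPM (0.0508). Camera gave the list an adjusted p of 0.421 (0.808 with an estimated correlation). All 5 genes stayed called without KO replicate 1, where 7 genes of the list were higher and 9 lower. In that fit 5793 of all 11677 genes tested were called. Without each of KO replicates 2 and 3 and WT replicates 1, 2 and 3 edgeR called 0 of the 5, with all 5 at an unadjusted p under 0.05. Over all 6 libraries limma-voom called 5 genes of the list and DESeq2 8.

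The ETS factors other than PU.1 were higher as a list and the other myeloid transcription factors lower. Of 15 ETS factors, 1 rose and 0 fell (3 and 0 adjusted over the list alone): Ets2, at 50.5 ± 7.71 against 22.8 ± 0.467 CPM, 2.22-fold (edgeR adjusted p = 0.0196). Camera called the list up (adjusted p = 0.0434), but not with an estimated correlation (adjusted p = 0.5 with an estimated correlation). Of 20 other myeloid factors, 0 rose and 1 fell by edgeR (1 and 4 adjusted over the list alone), the called one being Cebpa (181.1 ± 25.8 against 302.3 ± 17.7 CPM, adjusted p = 0.0418). With DESeq2 1 of these factors was higher and 4 were lower, and with limma-voom 0 and 1. Camera called this list down (adjusted p = 0.0324; adjusted p = 0.433 with an estimated correlation). The call of the ETS list was lost without KO replicate 1, WT replicate 1 or WT replicate 2 (camera adjusted p = 0.198, 0.0507 and 0.116). It was also lost after the GC and length correction (0.17) and with the replicate number as a block (0.0622). That of the other factors was lost without KO replicate 1 (0.159). Ets2 and Cebpa stayed called without KO replicate 1 only, with adjusted p between 0.0616 and 0.156 for Ets2 and between 0.0962 and 0.239 for Cebpa without each of the other 5 libraries. With KO replicate 1 left out, 5 ETS factors were higher and 2 lower, and 2 of the other factors were higher and 9 lower. Cebpa was also not called with upper-quartile factors (0.0886), without a filter (0.0511) or with a mean of at least 10 CPM (0.0508).

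Interferon-stimulated genes were higher in the libraries labelled KO. Of 27 tested, 9 rose and 0 fell, and adjusted over the list alone 16 were higher and 0 lower. Ifi27l2a rose 9.74-fold, from 2.01 ± 0.238 to 19.7 ± 6.35 CPM (edgeR adjusted p = 0.0147). Ifit3, which is induced by interferon, rose 4.62-fold to 5.44 ± 2.5 CPM, and Oas3, an enzyme of the antiviral oligoadenylate pathway, 3.54-fold to 43.5 ± 5.9 CPM. Irf7, a transcription factor of the interferon response, and Gbp2, a guanylate-binding protein, both chosen after their values were seen, rose 3.24-fold and 3.35-fold. Camera called the list up (adjusted p = 1.56e-08; adjusted p = 0.433 with an estimated correlation), and the call held without each single library, with adjusted p of 0.00154 or less. All 9 genes stayed called without KO replicate 1, where 14 genes of the list were higher and 2 lower. Ifit3 was not called by limma-voom (adjusted p = 0.0666). Without each of KO replicates 2 and 3 and WT replicates 1, 2 and 3 edgeR called 0 of the 9, all with an unadjusted p under 0.05, and over all 6 libraries DESeq2 called 14 genes of the list and limma-voom 8.

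Inflammatory cytokines and mediators were higher as a list, most of all in KO replicate 1. Of 20 tested, 2 rose and 1 fell by edgeR (5 and 1 adjusted over the list alone), 5 and 1 by DESeq2, and 2 and 1 by limma-voom. Nlrp3, the sensor of an inflammasome, rose 2.94-fold, from 24.2 ± 0.381 to 71.2 ± 3.81 CPM (edgeR adjusted p = 0.00322), and Ccl4, a chemokine gene that overlaps Ccl3 in the table's coordinates, 1.59-fold (adjusted p = 0.0443). Il1a, which encodes interleukin 1 alpha, fell from 5.27 ± 1.27 to 0.854 ± 0.486 CPM (adjusted p = 0.0464). Il1a was not called without a filter (0.0511) or with the GC and length correction, where its log2 difference was -1.82 instead of -2.61 (0.127), nor Ccl4 with upper-quartile factors (0.0607) or without a filter (0.0511). The mean log2 level of the list stood 1.61 above the WT mean in KO replicate 1, and 0.146 and 0.406 above it in KO replicates 2 and 3. Camera called the list up (adjusted p = 0.0102; adjusted p = 0.5 with an estimated correlation), fry did not (adjusted p = 0.0587), and without KO replicate 1 the call was lost (adjusted p = 0.227). All 3 genes stayed called without KO replicate 1, where 9 genes of the list were higher and 3 lower; Nlrp3 alone stayed without KO replicate 2, KO replicate 3, WT replicate 1 or WT replicate 3 (adjusted p = 0.0234, 0.037, 0.0433 and 0.0481), and none without WT replicate 2 (0.0638 for Nlrp3), with all 3 at an unadjusted p under 0.05.

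Genes of the ATF4 and unfolded protein response moved both ways. Of 22 tested, 3 rose and 1 fell, and adjusted over the list alone 8 were higher and 5 lower. Asns, the asparagine synthetase, rose 3.37-fold to 18 ± 4.32 CPM (edgeR adjusted p = 0.0208), Mthfd2, a mitochondrial folate enzyme, 2.51-fold (0.021) and Sesn2, a stress-induced regulator of mTORC1, 1.86-fold (0.0219). Cebpg, a transcription factor of the amino acid response, fell to 0.674 of its WT level (adjusted p = 0.0474; chosen after its values were seen). Slc7a11 and Atf3, also on this list, were not called by edgeR over all 6 libraries (adjusted p = 0.781 and 0.0892) but were lower without KO replicate 1 (5.46e-05 and 0.000205), and Atf3 also by DESeq2 (0.00934). Sesn2 lies within the listed range of other entries such as Zfp984, which also takes in Atp6v0d2 and is too wide to show that reads were shared. Camera gave an adjusted p of 0.305 (0.808 with an estimated correlation). All 4 genes stayed called without KO replicate 1, where 10 genes of the list were higher and 8 lower, and without each of the other 5 libraries edgeR called 0 of them, with all 4 at an unadjusted p under 0.05; over all 6 libraries DESeq2 called 12 genes of the list and limma-voom 4.

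Cell cycle genes were higher in the libraries labelled KO. Of 27 tested, 3 rose and 0 fell over all genes, and 26 were higher adjusted over the list alone. Top2a rose from 8.27 ± 1.28 to 46 ± 20.7 CPM (edgeR adjusted p = 0.0387), Cenpf, a kinetochore protein, from 1.06 ± 0.0777 to 6.01 ± 2.82 CPM, 5.66-fold (0.0376), and Mki67, the proliferation antigen, from 12.1 ± 2.41 to 62.9 ± 33.9 CPM, 5.18-fold (0.0464). The mean log2 level of the list stood 0.971, 3.01 and 2.94 above the WT mean in KO replicates 1, 2 and 3. Single genes departed from that order: Mki67 was at 45.6, 41.1 and 102 CPM and Cenpf at 4.84, 3.95 and 9.23 CPM in these libraries. The tested fibroblast markers stood at -1.01, 1.73 and 2.29 on the same scale. By limma-voom Top2a, Cenpf and Mki67 were at adjusted p of 0.0588, 0.0579 and 0.0579, and Mki67 was also not called by edgeR without a filter (0.053) or with a mean of at least 10 CPM (0.0531). Camera called the list up (adjusted p = 2.58e-11; adjusted p = 0.5 with an estimated correlation) and did so without each single library, but fry did not call it (adjusted p = 0.0587). Without KO replicate 1, 26 of the genes were higher. All 3 genes stayed called there, and without each of KO replicates 2 and 3 and WT replicates 1, 2 and 3 edgeR called 0 of the 3, all with an unadjusted p under 0.05; over all 6 libraries DESeq2 called 26 genes of the list and limma-voom 0.

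Genes of phagocytosis, efferocytosis and the lysosome were lower as a list. Of 25 tested, edgeR called 0 higher and 1 lower, and adjusted over the list alone 2 were higher and 10 lower. With DESeq2 2 were higher and 7 lower, and with limma-voom 0 and 2. Abcg1, a cholesterol exporter, fell to 0.6 of its WT level, from 548.1 ± 43.3 to 328.9 ± 49.3 CPM (edgeR adjusted p = 0.0471). Camera called the list down (adjusted p = 0.00849; adjusted p = 0.433 with an estimated correlation), and without KO replicate 1 the call was lost (adjusted p = 0.155), with 3 genes higher and 12 lower there. Abcg1 was not called with a mean of at least 10 CPM (0.0546). It stayed called without KO replicate 1 (0.000273) and not without KO replicate 2 or 3 or WT replicate 1, 2 or 3 (0.134, 0.172, 0.172, 0.234 and 0.154).

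Genes of MHC class II presentation showed no common direction. Of 12 tested, 1 rose and 1 fell (2 and 1 adjusted over the list alone). Rfx5, a transcription factor of MHC class II promoters, rose 1.83-fold to 16.9 ± 0.574 CPM (edgeR adjusted p = 0.0297), and Ctss fell to 0.391 of its WT level. The list had a median log2 difference of -0.19, a mean of 0.13 and the camera direction down, with an adjusted p of 0.76 (0.84 with an estimated correlation). Both genes stayed called without KO replicate 1, where 2 genes of the list were higher and 5 lower, and without each of the other 5 libraries edgeR called 0 of them, with both at an unadjusted p under 0.05; over all 6 libraries DESeq2 called 3 genes of the list and limma-voom 2.

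Among the metabolic lists, Hilpda, a lipid droplet protein induced by hypoxia, fell to 0.47 of its WT level (5.88 ± 0.215 against 12.5 ± 2.02 CPM, edgeR adjusted p = 0.0364). It was the 1 lower gene of 22 in the glycolysis and hypoxia list by edgeR, where 0 rose, with the same counts adjusted over the list alone and a camera adjusted p of 0.337 (0.808 with an estimated correlation). With DESeq2 1 gene of that list was higher and 1 lower. Hilpda stayed called without KO replicate 1 (0.00137), where 4 genes of the list were higher and 5 lower, and not without KO replicate 2 or 3 or WT replicate 1, 2 or 3 (0.134, 0.155, 0.171, 0.234 and 0.0957). Of 22 cholesterol synthesis genes, edgeR called 0, also adjusted over the list alone, with 4 at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 0. Hmgcs1, the synthase at the head of that pathway, had the smallest p, at 39.5 ± 1.73 against 60.6 ± 8.48 CPM (adjusted p = 0.059; 0.00288 by DESeq2). The GC and length correction moved its log2 difference from -0.62 to -0.22 (0.509). Camera gave that list an adjusted p of 0.428 (0.84 with an estimated correlation), and of 0.0211 in the direction up without KO replicate 1, where 14 genes were higher and 2 lower.

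Platelet and megakaryocyte markers were lower in the libraries labelled KO. Of 5 tested, 0 rose and 3 fell (0 and 4 adjusted over the list alone): Itga2b, Gp1bb and Gp9, of which the last was chosen after its values were seen. Gp1bb, a chain of the von Willebrand factor receptor, had 0, 0 and 1 counts in KO replicates 1, 2 and 3 against 169 in the WT libraries together, a 188-fold difference (95% counting interval 33.2 to 7460; edgeR adjusted p = 0.0147). Gp9, another chain of that receptor, had 2, 0 and 0 counts against 87, a 48.3-fold difference (13 to 405; adjusted p = 0.0452). Pf4, the platelet chemokine, was at 44.9, 16.2 and 14.5 CPM against 19 ± 2.46 CPM (adjusted p = 0.598; chosen after its values were seen). Camera called the list down (adjusted p = 0.000999; adjusted p = 0.433 with an estimated correlation) and did so without each single library, with adjusted p of 0.00441 or less. All 3 genes stayed called without KO replicate 1, and without each of the other 5 libraries edgeR called 0 of them, with all 3 at an unadjusted p under 0.05; over all 6 libraries DESeq2 and limma-voom each called 3 genes of the list.

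Genes typical of resident large peritoneal macrophages and of small peritoneal macrophages and monocytes gave single calls. Of 13 genes of the large type, 2 rose and 0 fell (3 and 1 adjusted over the list alone): Icam2, an adhesion molecule, 2.48-fold to 3.79 ± 0.517 CPM (edgeR adjusted p = 0.0454), and Itga6, an integrin chain that binds laminin, 1.76-fold to 126.5 ± 16.3 CPM (0.0489). Of 11 genes of the small type, 1 rose and 0 fell (2 and 1 adjusted over the list alone), the called gene being Cx3cr1 at 25-fold. By DESeq2, 4 genes of the large type were higher and 2 lower, and 3 of the small type were higher and 1 lower. The camera adjusted p was 0.744 for the large type and 0.697 for the small type (0.808 for each with an estimated correlation). Of 16 alternative activation genes, edgeR called 0, also adjusted over the list alone, with 6 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0, and camera gave an adjusted p of 0.982 (0.983 with an estimated correlation). Clec10a, a lectin receptor on that list and on the small-type list, was at 39.2 CPM in KO replicate 1 and at 7.29 and 7.35 CPM in replicates 2 and 3, against 3.32 ± 0.868 CPM (adjusted p = 0.144; 0.00769 by DESeq2). All 3 called genes stayed called without KO replicate 1, where 4 genes were higher and 3 lower in each of the large-type and small-type lists, and 3 higher and 3 lower among the alternative activation genes. Icam2 was not called without a filter (0.0602), nor Itga6 with a mean of at least 10 CPM (0.0508). Cx3cr1 stayed called without WT replicate 2 (adjusted p = 0.0364) and not without KO replicate 2 or 3 or WT replicate 1 or 3 (0.0574, 0.0738, 0.0893 and 0.0691), and Icam2 and Itga6 were not called without any of the libraries other than KO replicate 1 (adjusted p of 0.11 or more).

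Of 18 dissociation and immediate early genes, which respond quickly to handling of cells, edgeR called 0, also adjusted over the list alone, with 2 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. Atf3, a stress-induced transcription factor, had the smallest p, at 373 ± 67.9 against 550.1 ± 1.31 CPM (adjusted p = 0.0892; 0.00934 by DESeq2). Camera gave an adjusted p of 0.305 (0.808 with an estimated correlation), and of 0.00636 in the direction down without KO replicate 1, where 2 genes were higher and 11 lower. KO replicate 1 stood 0.466 above the WT mean where KO replicates 2 and 3 stood at -0.924 and -0.729.

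The remaining marker lists had fewer than 5 tested members and received counts only. Of 4 osteoclast markers, 0 rose and 1 fell (0 and 2 adjusted over the list alone), the called one being Ctsk, which stayed called without KO replicate 1 (1.05e-05) and not without KO replicate 2 or 3 or WT replicate 1, 2 or 3 (0.0822, 0.0889, 0.103, 0.156 and 0.108). By edgeR, 0 were called of 1 B cell, 3 T and NK cell, 4 neutrophil, 2 eosinophil, 1 mast cell, 4 fibroblast, 2 endothelial and 1 erythroid marker. At an unadjusted p under 0.05 there were 0, 0, 2, 1, 1, 1, 1 and 0 of these in the same order, DESeq2 called 1 neutrophil and 1 endothelial marker and 0 of the others, and limma-voom called 0. Adjusted over the list alone, 1 neutrophil and 1 endothelial marker were lower, 1 mast cell marker was higher, and 0 of the other lists were called. Among members with a mean of at least 1 CPM, those with the smallest p in their list were Cd79b (2.01 against 1.19 CPM, adjusted p = 0.326), Cd4 (16.5 against 25.6, 0.594), S100a8 (2.59 against 6.21, 0.0774; 0.00268 by DESeq2), Ccr3 (0.852 against 2.25, 0.205), Col6a3 (4.91 against 1.065, 0.198) and Pecam1 (0.758 against 1.88, 0.0606; 0.0255 by DESeq2). KO replicate 1 weighed on several of these means: without it the log2 difference went from -0.63 to -0.12 for Cd4, from 0.75 to 0.24 for Cd79b and from -1.39 to -0.96 for Ccr3 (adjusted p = 0.0349), and the GC and length correction put Ccr3 at -0.37. The fibroblast markers moved apart within the libraries labelled KO: Col1a2, a collagen chain, was at 1.21, 10.5 and 15.9 CPM in KO replicates 1, 2 and 3 against 2.73 ± 0.909 CPM, and Pdgfra, a growth factor receptor below the level for a test, at 0.116, 2.58 and 3.67 against 0.277, 0.111 and 0.17 CPM, both chosen after their values were seen. With KO replicate 1 left out, all 4 tested fibroblast markers were higher, as were 1 of the neutrophil, 1 of the osteoclast and 1 of the mast cell markers. Lower there were 3 neutrophil, 3 osteoclast, 1 T and NK cell, 1 eosinophil, 1 endothelial and 1 erythroid marker. No dendritic cell and no mesothelial marker reached the level needed for a test.

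**Figure D3:**
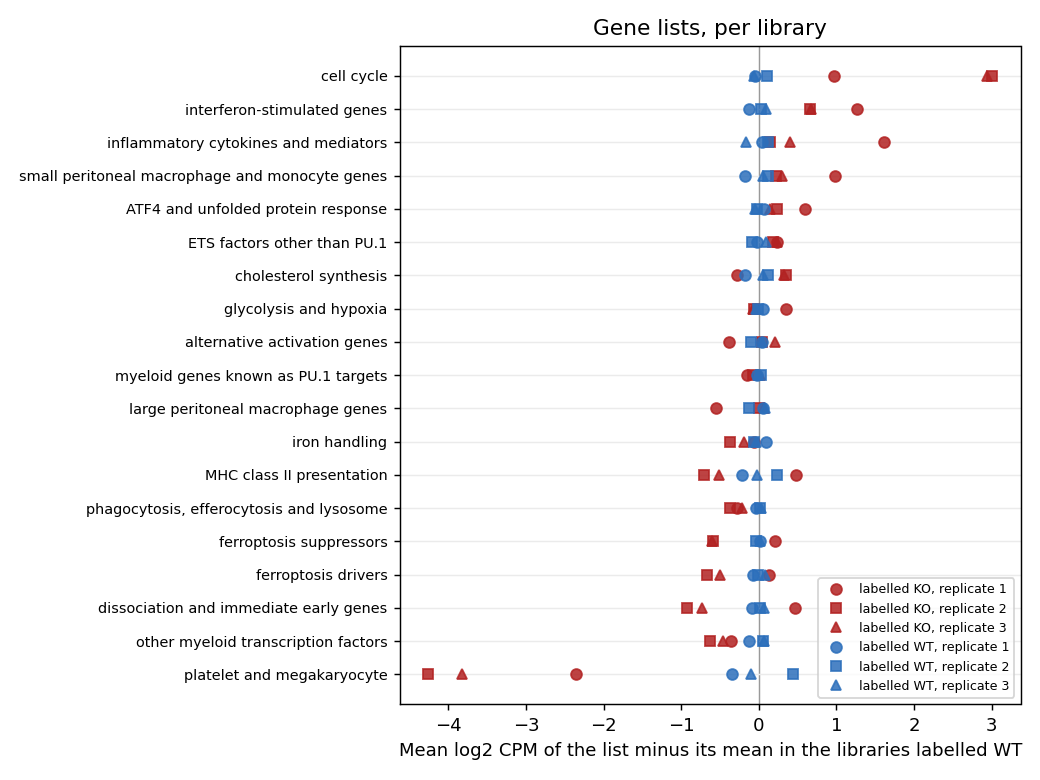
Mean log2 CPM of each tested gene list in each library, minus the mean of the WT-labelled libraries (x axis), with KO-labelled libraries in red, WT-labelled in blue, and circle, square and triangle for replicates 1, 2 and 3. The cell cycle list lies at 0.971, 3.01 and 2.94 in KO replicates 1, 2 and 3, and the platelet list at -2.35, -4.26 and -3.83.

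Pathway terms paired with the genes in the deposited table were tested with camera, which called 41 of 2400, 36 higher and 5 lower. With an estimated correlation camera called 0 terms, each term named here having an adjusted p of 1 with an estimated correlation. The higher terms included formation of a pool of free 40S subunits (90 genes, adjusted p = 5.83e-06), type I interferon signalling (18 genes, 1.3e-05, with 5 genes called higher) and mitotic sister chromatid segregation (30 genes, 4.01e-05). The lower terms were production of reactive oxygen and nitrogen species in phagocytes (26 genes, 0.00502), insulin receptor recycling (20 genes, 0.012), transferrin endocytosis and recycling (24 genes, 0.012), collecting duct acid secretion (17 genes, 0.0248) and the response to platelet calcium (51 genes, 0.0321). Apart from the platelet term, each had 1 or 2 genes called lower and a median log2 difference between -0.284 and -0.269. Terms can share genes, and the overlap of these terms was not analysed. The ferroptosis term (37 genes) was not called (adjusted p = 0.515), with 0 genes higher and 1 lower. Without KO replicate 1, 54 terms were called, 52 higher and 2 lower, and the 5 lower terms above were not among them (0.172, 0.235, 0.35, 0.428 and 0.142).

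Counts of the 85 ribosomal protein genes made up 3.22% ± 0.306 of each library labelled KO and 2.39% ± 0.244 of each labelled WT (SD, n = 3), a difference of 0.83 percentage points (exact permutation test, 2-sided p = 0.1). The 10 most abundant genes took 18.4% ± 2 and 21.8% ± 1.38 (exact permutation p = 0.1). With 20 assignments, 0.1 is the smallest p this test can give. The share of mitochondrial genes was not analysed here.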

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

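The correction for GC content and transcript length, the fit without X and Y genes and the alternatives for pathway terms were chosen after the data were seen; all others were set before. The 379 called genes became 376 with RLE factors, 382 with upper-quartile factors, 355 with limma-voom, 293 without a filter and 392 without X and Y genes. DESeq2, run on 15450 genes with its own filter so that tool and filter both changed, gave 1344, the GC and length correction 723, and a mean of at least 10 CPM, which tests fewer genes, 229. Stricter thresholds gave 234 (2-fold added) and 15 (adjusted p under 0.01). Leaving out 1 library gave 5 (WT replicate 2) to 5793 (KO replicate 1), and the cause was not tested. The 2 called ferroptosis genes became 8 with DESeq2 (2 higher and 6 lower), 5 with the correction (2 higher and 3 lower) and 0 to 32 with 1 library left out. Both genes kept an unadjusted p under 0.05 with 1 library left out, and the cause was not tested. Spi1 was called in none of the fits, with a log2 difference of -0.20 to -0.05. The 7 called lists were 5 with fry, which did not call the cell cycle and inflammatory lists (0.0587 each), 6 without a filter, 6 to 7 with 1 library left out, and 0 with an estimated correlation. Without KO replicate 1, 3 of the 7 stayed called (interferon, cell cycle, platelet) and 3 others were called: ferroptosis suppressors (0.00636), cholesterol synthesis (0.0211) and dissociation genes (0.00636). The 41 called terms numbered 39 to 54 with 1 library left out and 0 with an estimated correlation. For the calls lost with an estimated correlation the cause was not tested. The estimated correlation of the other myeloid transcription factors, 0.00915, lay below the preset 0.01. Their camera adjusted p still went from 0.0324 to 0.433, so a correlation above the preset does not account for that loss. The phagocytosis, efferocytosis and lysosome list, with an estimated correlation of 0.017, went from 0.00849 to 0.433 by camera. A call lost with an estimated correlation is therefore not shown to be lost through correlation between genes. The difference in ribosomal protein share was 0.83 percentage points over all genes and 0.848 over genes with a mean of at least 10 CPM. The replicate numbers are not said to pair samples, and the deviations of same-numbered libraries from their group means correlated at -0.162, 0.246 and -0.271. With 3 libraries per group and KO replicate 1 standing apart from its group, these values cannot decide whether the numbers pair samples. With replicate number as a block, edgeR called 0 genes and 0 ferroptosis genes (1976 genes at an unadjusted p under 0.05), camera 6 lists and 60 terms, and the cause was not tested; DESeq2 and limma-voom were not run with the block. No direction of a named gene reversed: over all alternatives, 437 results kept their side of the threshold, 221 were no longer past it and 16 came past it. The alternatives for a table of normalized values were not run, since the table held counts. At this depth and spread, 24% of simulated 2-fold changes were recovered over 11424 genes, so uncalled genes may have changed by such sizes.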

Other observations

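The tests of a mislabelled library, of a mixture, of Y-linked counts in KO replicate 1, of the genes left after the GC and length correction and of a partial deletion of Spi1 were chosen only after the result was seen; the tests of variance explained by GC content and length, of the X chromosome, of the region around Spi1 and of other splits were set beforehand. Some limits were also changed after a first value was known. For the genes left after the correction, the first limit asked that most of the 1220 genes remain, which 529 did not meet, and it was replaced by a comparison with the other libraries. The limit first set for the mixture was not met by its 85 genes, and the test of genes above the range was added then. The test of a mislabelled library gained the condition that the share exceed that of genes as far out the other way.

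Another 8 of the 379 called genes, chosen after their values were seen, lie outside the lists. Lower in the libraries labelled KO were Fabp4, a fatty acid carrier (88 ± 9.72 against 280.5 ± 15.6 CPM), Plin2, the coat protein of lipid droplets (645.2 ± 69.6 against 1630 ± 69.2), Alas1, the first enzyme of haem synthesis (140.3 ± 11 against 461.4 ± 63.3), Clec7a, the receptor for fungal glucans (262.2 ± 77.4 against 922.1 ± 169), and Mmp12, the macrophage elastase (1402 ± 486 against 4168 ± 533). Higher were Csf1, the macrophage growth factor (32.8 ± 5.01 against 5.97 ± 1.14), Ifitm3, an antiviral membrane protein (333.8 ± 66.9 against 65.3 ± 5.94), and Ccnd1, cyclin D1 (133.2 ± 42.4 against 28.1 ± 0.958). The edgeR adjusted p of these 8 genes lay between 0.00634 and 0.0471. All 8 stayed called without KO replicate 1, Fabp4 and Ifitm3 without KO replicate 2, and Fabp4 and Alas1 without WT replicate 1. They were not called without KO replicate 3, WT replicate 2 or WT replicate 3, where the adjusted p lay between 0.0635 and 0.239.

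Some genes set KO replicate 1 apart from the other 5 libraries, again chosen after their values were seen. Ccr2, the monocyte chemokine receptor, was at 64.1 CPM there against 1.54 and 2.5 CPM in KO replicates 2 and 3 and 2.27 ± 0.413 CPM in the WT libraries (edgeR adjusted p for the groups 0.259). Acod1, which makes itaconate, was at 69.8 against 5.34, 4.48 and 3.52 ± 0.189 CPM (0.22), and Saa3, an acute phase gene, at 27.6 against 0.719, 1.35 and 0.62 ± 0.495 CPM (0.225). Vcam1, an adhesion molecule, was at 0.881 CPM against 46.4, 69.4 and 69.6 ± 29.7 CPM (0.672).

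The first pattern is that KO replicate 1 stood apart from KO replicates 2 and 3. A WT library under a wrong label is argued against: over 2189 autosomal genes that separate KO replicates 2 and 3 from WT, KO replicate 1 lay on the KO side in 18.8%, against 1.01% to 3.43% for held-out WT libraries and 4.8% as far out the other way, although its median position was 0.0117 on a scale from 0 for WT to 1 for the other KO libraries. Material of the WT libraries mixed in is argued against by its Y-linked counts, 8 in all, 0.314% of the WT level (95% counting interval 0.135 to 0.619). A mixture of KO-like and WT-like material is argued against for the 34 genes 2-fold above all 5 other libraries (at most 1 in any other library). WT-like cells without Y-linked transcripts remain open, since 85 genes lay outside the range on either side and KO replicate 2 had 109. Single top genes went both ways. In KO replicate 1, Cx3cr1, Marcksl1 and Nlrp3 were at 53.7, 64.5 and 69.7 CPM. KO replicates 2 and 3 had 50.3 to 52.4, 61.3 to 62 and 68.3 to 75.5 CPM of them. Dmpk, Spn, Ifi27l2a, Dmwd, Lmnb1 and Top2a were lowest in KO replicate 1 among the KO libraries, with Lmnb1 at 9.03 against 37.7 and 29.5 CPM. All of these were picked from the genes called over all 6 libraries, so they do not decide it. GC content and transcript length explained 27.1% of the variance between KO replicate 1 and the other KO libraries, 23.2% between those and WT, 16% between KO and WT, and 2.54% between KO replicate 1 and WT. Correction for them removed most of the genes 2-fold apart, from 1220 to 529, with at most 26 for any other library, which argues against this bias as the whole difference but leaves a large part of it open; no biological explanation was tested.

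The second pattern is the near absence of Y-linked transcripts from every library labelled KO. One candidate explanation is that cells of female mice were compared with cells of male mice, in which case sex may also have moved other genes. Called genes were not over-represented on the X chromosome, 9 of 353 with an odds ratio of 0.757 (95% interval 0.34 to 1.47, Fisher's exact p = 0.544). Autosomal effects of sex, or effects on only a few X-linked genes, would not show in that test, so it does not argue against a difference of sex. Sex and label would also be the same split of the libraries. Effects of sex and of PU.1 therefore cannot be told apart for the other called genes. A loss of the Y chromosome in culture was not tested.

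The third pattern is that Spi1 was not called lower in the libraries labelled KO. A deletion of some exons with the rest still counted could leave the gene's count near the WT level, and the log2 difference of -0.103 does not decide this, since reads over single exons were not analysed here. If DNA of another strain around the altered allele had moved nearby genes, calls would gather there, but 2 of 55 genes within 10 Mb were called, with an odds ratio of 1.1 (95% interval 0.129 to 4.2, Fisher's exact p = 0.705), too wide to decide. Whether the deletion took place in these cells was not tested.

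For the count of called genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the real split gave 379 genes by edgeR, and 1 split, the real one, reached that number. The highest count of the other splits was 0 (2596 genes had an unadjusted p under 0.05 in the real split, and other tools were not run on the splits).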
